A study of Oryza sativa Japonica Group with 10 samples.

How the data were processed

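Polyadenylated RNA from rice roots was measured in 10 libraries, 3 of root tip and 2 of mature root on each of 2 sampling days. Per the labels' protocols, seeds germinated for 5 days in the dark, seedlings of 12 days went into hydroponics with the whole plant in the light, and tips were cut from the rest of the root 2 or 6 days later. Per the same protocols, each replicate pooled 6 plants, about 2 µg of total RNA entered an Illumina mRNA library, fragments of about 200 bp were selected on a gel and 18 cycles of PCR followed. No molecular identifiers are mentioned, so counts are reads and not independent molecules, and counting intervals and floors cover counting error only. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

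The authors deposited a table of whole-number counts per gene for all libraries, without normalization, per the file headers and the values. The submitters' processing notes name TopHat 1.3.1, Cufflinks 1.0.3, SAMtools 0.1.12a and Bowtie, without role or order; the genome build and the counting tool are not given in the sources used here. The table holds 33486 rows: 22303 gene models, 8573 gene models with the ending -ext and 2610 rows named as putative transcribed regions, which carry no description. What the ending -ext stands for is not given in the sources used here, and such rows were kept under their full names. Gene descriptions were those in the deposited table. Columns were matched to libraries through the sample descriptions, and every column with values per sample belonged to 1 of the 10 libraries. No genome was used, and no coordinates are reported.

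Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Rows were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 19234. Libraries were scaled by TMM, dispersions were estimated over all 10 libraries without covariates, and a quasi-likelihood model with 1 mean per group gave 6 contrasts: tip against mature root as the mean of both days and on each day, day 6 against day 2 in each tissue, and the difference of the tissue contrast between days. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and calls with an absolute log2 fold change of at least 1 were also counted. CPM values are TMM-scaled, and correlations and principal components used log2 CPM with a prior count of 2. All groups share an estimate of spread, since mature root has 2 libraries per day. Adjusted p-values rest on these pools, which the labels call independent biological replicates. Counting intervals cover reads only, and bootstrap intervals resample genes and not pools.

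Gene lists were fixed as patterns on descriptions before the data were examined; 31 of 32 had at least 5 tested members. Each was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists within each contrast, then with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the members themselves change. The named genes followed a rule set at the same time. For the tissue contrast it took the 6 largest log2 fold changes in each direction among called, described genes with at least 10 CPM in the higher tissue and no overlap between tissues on both days. It added the 2 members with the smallest p in the direction of each passing list for that contrast and both time contrasts, and the 5 smallest p for the difference between days; the 8 largest changes per direction foreseen for time were not taken, as nothing was called. A gene with 0 counts in a tissue is given as at least so many fold lower, from a floor of 3 counts over the group (0.29 CPM in tip and 0.27 CPM in mature root); with 1 to 3 counts the ratio has an exact 95% Clopper-Pearson interval.

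The alternatives were DESeq2 1.42.0 size factors, library totals as scaling, no filter on low counts, at least 5 CPM in 2 libraries, robust dispersion, the DESeq2 test, the replicate number as a block, a fit of only the compared groups, and each library left out in turn. When a mature root library is left out, the other one of its group is assumed to vary like the other groups. All libraries thinned to the lowest total and voom with sample weights were added after seeing the data.

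The steps were tested on simulated counts with 200 changed genes, 100 at each fold. They used the real library sizes, each gene's mean over all 10 libraries and the dispersion trend. The spread of single genes around that trend was left out, so recovery and false calls in the real data can differ. In the tissue contrast over both days, simulated on 18330 genes, 38% of the 4-fold and 90% of the 16-fold changes were recovered, with 7 false calls. The shares were 3% and 61% for the tissue contrast on day 2 (18337 genes), 10% and 74% on day 6 (18346 genes), 22% and 79% for time in the tip (18367 genes), 5% and 57% for time in mature root (18412 genes) and 0% and 20% for the difference between days (18405 genes). In each of these simulations 0 unchanged lists passed camera. Genes were drawn independently there and these lists were random sets of genes. The simulations therefore do not show how camera treats lists whose members vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.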

Results

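Messenger RNA was sequenced from the root tips and from the remaining, mature part of the root of rice seedlings, cultivar Nipponbare, a japonica reference cultivar. The seedlings had been moved at an age of 12 days into hydroponics, that is, into nutrient solution without a solid substrate, and roots were taken 2 or 6 days after the transfer. The plants of day 6 were thus older, so days in hydroponics, plant age and sampling occasion cannot be told apart. The tip sample held the meristem and the elongation zone, and the mature root sample held the rest of the root system. Each library was made from a pool of 6 plants. There were 3 root tip pools and 2 mature root pools on each day, 10 libraries in all, and the labels call the pools independent biological replicates. The tip libraries held 986907 to 2001408 counts on day 2 and 1428128 to 2560074 on day 6. The mature root libraries were deeper, with 2161392 to 2776544 counts on day 2 and 2648858 to 3286439 on day 6. A total of 3 counts corresponded to between 0.913 and 3.04 CPM per library (CPM, counts scaled to a common library total), so genes below a few CPM were measured with large counting error. Of 33486 genes and transcribed regions in the table, 19234 had enough counts to be tested.

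Libraries of the same tissue resembled each other more, on average, than libraries of different tissues. The Pearson correlation of log2 CPM across genes, which are not independent replicates, averaged 0.81 over the 8 pairs of libraries of the same group and 0.791 over the 13 pairs of the same tissue on different days. It averaged 0.676 over the 24 pairs of a tip with a mature root library, with a highest value of 0.744. The lowest pair of the same tissue on different days had 0.726, so the ranges overlapped. The first principal component held 34.6% of the variance and had negative values in the 6 tip libraries and positive values in the 4 mature root libraries. Replicates of the same group were far apart compared with counting error, with a chi-square per degree of freedom between 17.5 and 35.6 for the 8 replicate pairs, and the common biological coefficient of variation was 0.589.

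**Figure D1:**
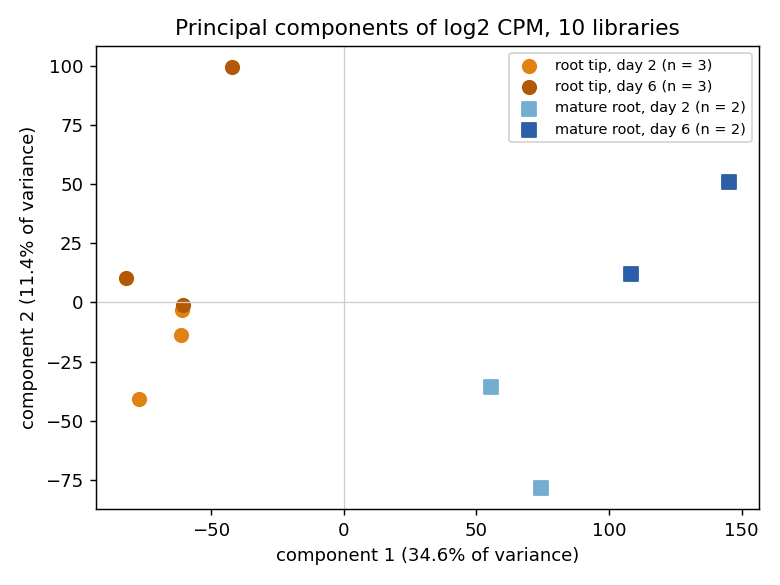
Principal components of log2 CPM over the 19234 tested genes, component 1 (34.6% of the variance) on the horizontal axis and component 2 (11.4%) on the vertical axis. Each point is 1 of the 10 libraries, circles for root tip and squares for mature root; the 6 tip libraries lie to the left of 0 and the 4 mature root libraries to the right.

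The first comparison asked which genes differed between the tip and the mature root over both days. Cytosolic ribosomal protein genes were higher in the tip as a list. The Casparian strip and suberin, mineral nutrient transporter, iron and metal, cytokinin, gibberellin, ethylene, WRKY and NAC lists were lower there, as was the photosynthesis list, which had the largest median difference of the lists tested. The lignin and pathogenesis-related lists were lower by camera and by fry, but did not pass camera with an estimated correlation (adjusted p = 0.108 and adjusted p = 0.145). Of the 19234 genes, 611 were higher and 1734 lower in the tip by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2314 of these 2345 differed at least 2-fold. The count rested on the mature root libraries: without mature root day 2 replicate 1 or 2 it was 1337 or 1015, and without mature root day 6 replicate 1 or 2 it was 845 or 1363. Leaving out a mature root library also lowered the share of calls that were higher in the tip from 26.1% to between 9.85% and 12.6%. With the replicate number as a block 276 genes were higher and 990 lower (21.8% higher). DESeq2 called 1214 higher and 2355 lower (34%), and edgeR without the filter on low counts 1324 and 2739 (32.6%). Of the 31 gene lists tested, 7 were higher and 11 lower in the tip by the camera set test, which compares a list with all other genes, and 10 of these 18 passed with an estimated correlation between genes.

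Cytosolic ribosomal protein genes were the list with the most members called higher in the tip. Of 229 members tested, 90 were higher and 2 lower, and 140 were higher and 7 lower when adjusted over the list alone. The median log2 fold change was 1.01 (camera adjusted p = 1.77e-20, and adjusted p = 0.0375 with an estimated correlation). The list took 8.79% ± 0.497 of the counts in tips on day 2 (SD, n = 3) and 9.85% ± 0.993 on day 6 (SD, n = 3), against 5.84% ± 0.286 and 3.93% ± 0.0656 in mature root (SD, n = 2 each). LOC_Os08g13690-ext, annotated as a large-subunit protein L7, had 1800 ± 465 CPM in the tip (SD, n = 6) and 724 ± 189 CPM in mature root (SD, n = 4), a log2 fold change of 1.33 (SE 0.21, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.55e-03). LOC_Os05g48320-ext, another large-subunit protein gene, had 618 ± 272 and 159 ± 34.9 CPM. Without mature root day 2 replicate 1 or 2 the number of members called higher was 43 or 25, and without mature root day 6 replicate 1 or 2 it was 32 or 33. Ribosomal protein genes have near-identical copies that can share reads, so values of single members are uncertain.

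**Figure D2:**
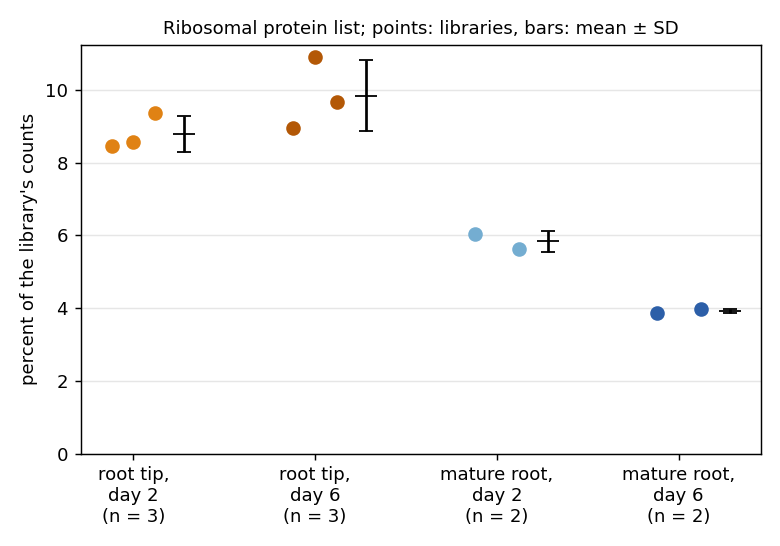
Share of each library's counts in the cytosolic ribosomal protein list, in percent, by group. Points are libraries and bars the mean ± SD (n = 3 per root tip group, n = 2 per mature root group); the 6 tip libraries lie between 8.45% and 10.9%, and the 4 mature root libraries between 3.88% and 6.04%.

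Tubulins, DNA replication proteins, kinesins and core histones lay higher in the tip as sets with the preset correlation, but none of these lists passed with an estimated correlation, and cyclins did not pass with either. By fry the tubulins, DNA replication proteins, kinesins and cyclins passed (highest adjusted p = 0.0226), and core histones did not (adjusted p = 0.072). Tubulins, the subunits of microtubules, had 3 of 18 members higher (4 adjusted over the list alone), a median log2 fold change of 0.5, a camera adjusted p = 0.0125 and an adjusted p = 0.0983 with an estimated correlation. The tubulin LOC_Os02g07060-ext had 1320 ± 385 CPM in the tip (SD, n = 6) and 418 ± 89.7 CPM in mature root (SD, n = 4), and the tubulin LOC_Os01g59150-ext had 659 ± 147 and 325 ± 76.8 CPM. These genes can also share reads with close copies. LOC_Os01g59150-ext lost its call without root tip day 2 replicate 1, mature root day 2 replicate 1 or 2, or mature root day 6 replicate 1 (adjusted p up to 0.128), and in each of these cases 1 tubulin was called higher. It also lost it with library totals as scaling and with the replicate number as a block. DNA replication proteins had 2 of 43 members higher (0 adjusted over the list alone), a median of 0.58 and a camera adjusted p = 9.53e-04, with an adjusted p = 0.0685 with an estimated correlation. Those 2 were LOC_Os03g03650, a subunit of DNA polymerase delta, at log2 2.01 (SE 0.58), and LOC_Os02g30800-ext, the catalytic subunit of DNA polymerase epsilon, at log2 1.55 (SE 0.45). Kinesins and spindle proteins had 2 of 55 members higher (0 adjusted over the list alone), a median of 0.66 and a camera adjusted p = 2.85e-04, with an adjusted p = 0.155 with an estimated correlation. The spindle assembly factor described as targeting protein for Xklp2, LOC_Os02g10690-ext, stood at 97.6 ± 67.7 CPM in the tip (SD, n = 6) against 23.7 ± 1.98 CPM (SD, n = 4), and the spindle checkpoint gene MAD2, LOC_Os04g40940-ext, stood at 46.6 ± 11 against 18.1 ± 2.05 CPM. LOC_Os03g03650, LOC_Os02g30800-ext, LOC_Os02g10690-ext and LOC_Os04g40940-ext each lost their call when any 1 of the 4 mature root libraries was left out. All of these but LOC_Os02g10690-ext also lost it with library totals as scaling, without the filter on low counts, with the replicate number as a block overall or within day, with thinned libraries, and without root tip day 2 replicate 1 or 3 or root tip day 6 replicate 1. LOC_Os03g03650 and LOC_Os02g30800-ext lost it without root tip day 6 replicate 2 as well, LOC_Os03g03650 with voom, and LOC_Os02g30800-ext without root tip day 2 replicate 2. Core histones, with a median of 0.55 and a camera adjusted p = 0.0127 but an adjusted p = 0.396 with an estimated correlation, had 0 of 34 members called higher and 1 lower (8 and 1 adjusted over the list alone). The 2 histone genes with the smallest p in this direction, LOC_Os03g53190-ext and LOC_Os03g06670-ext, did not pass, with log2 fold changes of 0.95 (SE 0.3) and 1.55 (SE 0.49) and Benjamini-Hochberg adjusted p of 0.0562 and 0.0582 in edgeR's quasi-likelihood test. The histone list also lost its call without mature root day 2 replicate 1, at an adjusted p = 0.0561.

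Cell wall and cell surface genes of the tip went both ways. Expansins, which loosen the wall during growth, had 3 of 32 members higher and 3 lower (9 and 3 adjusted over the list alone), with a median of 0.85, a camera adjusted p = 0.0105 and an adjusted p = 0.151 with an estimated correlation. LOC_Os03g01260-ext stood at 204 ± 59.1 CPM in the tip (SD, n = 6) against 54.4 ± 27.8 CPM in mature root (SD, n = 4), and LOC_Os05g15690 at 17.7 ± 11.5 against 2.14 ± 3.12 CPM. Both calls were lost without mature root day 2 replicate 1 or mature root day 6 replicate 1, and that of LOC_Os03g01260-ext also without mature root day 2 replicate 2. With these libraries left out 0, 0 and 1 expansins were called higher, and 5 without root tip day 2 replicate 1 or 2. LOC_Os05g15690 also lost its call with voom. The root cap and arabinogalactan list had 1 of 30 members higher and 1 lower (0 and 1 adjusted over the list alone), with a median of 0.52, a camera adjusted p = 0.0205 and an adjusted p = 0.408 with an estimated correlation. It lost its call without root tip day 2 replicate 1 (adjusted p = 0.112) and without mature root day 6 replicate 1 (adjusted p = 0.0649). The member called higher was LOC_Os01g73700, annotated as a root cap and late embryogenesis related protein, at log2 3.7 (SE 1.06). LOC_Os01g73700 lost its call when any 1 of the 4 mature root libraries, root tip day 2 replicate 1 or root tip day 6 replicate 2 was left out, and with voom. Another member, the fasciclin domain gene LOC_Os09g30486, had a log2 fold change of 1.32 (SE 0.42) that did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0598).

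Outside the lists, the largest differences in favour of the tip were in genes of varied description. This ranking covers called, described genes of at least 10 CPM in the tip, without overlap between the tissues on both days. The phytase gene LOC_Os04g24340-ext, of an enzyme class that releases phosphate from phytate, had 50.4 ± 24.4 CPM in the tip (SD, n = 6) and 1.55 ± 1.33 CPM in mature root (SD, n = 4), a 32.3-fold difference. The armadillo repeat gene LOC_Os06g46995 had 74.5 ± 47.6 and 2.75 ± 1.15 CPM. The DJ-1 family gene LOC_Os01g11860 had 20.7 ± 17 and 0.811 ± 0.965 CPM. The F-box gene LOC_Os04g30320 had 101 counts over the tip libraries and 1 over the mature root libraries, a ratio of 108 with a 95% counting interval from 19 to 4310. The WD repeat gene LOC_Os08g18150, at 11.1 ± 19.8 CPM in the tip, and the stress responsive gene LOC_Os12g08340, at 16 ± 29.4 CPM, varied between tip libraries by more than their mean. Both lost their call when any 1 of the 4 mature root libraries was left out, and with voom. LOC_Os08g18150 also lost it without replicate 2 of root tip day 2 or of root tip day 6, and LOC_Os12g08340 with the replicate number as a block.

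The Casparian strip and suberin list and the lignin list were lower in the tip by camera. The Casparian strip and suberin list, which covers the water-tight wall deposits of the endodermis and exodermis, had 4 of 11 members lower and 0 higher (8 and 1 adjusted over the list alone), with a median log2 fold change of -3.03 (camera adjusted p = 6.02e-06, and adjusted p = 0.0322 with an estimated correlation). LOC_Os08g44360, described as male sterility protein 2, a family of fatty acyl reductases, had 2.86 ± 2 CPM in the tip (SD, n = 6) and 285 ± 99.1 CPM in mature root (SD, n = 4), a log2 fold change of -6.57 (SE 0.55). The glycerol-3-phosphate acyltransferase gene LOC_Os02g02340 had 2 counts in the tip libraries and 128 in mature root, a ratio of 59.8 with a 95% counting interval from 16.2 to 499. Lignin and phenylpropanoid enzymes had 12 of 57 members lower and 1 higher (21 and 2 adjusted over the list alone), with a median of -1.11, a camera adjusted p = 2.17e-04 and an adjusted p = 0.108 with an estimated correlation. LOC_Os05g35290, a phenylalanine ammonia-lyase, the entry enzyme of the pathway, had 22.5 ± 10.8 CPM in the tip and 256 ± 264 CPM in mature root. The caffeoyl-CoA O-methyltransferase gene LOC_Os08g38910-ext had 0 counts in the 6 tip libraries together and 183 in mature root, which made it at least 57-fold lower in the tip with a floor of 3 counts over the group. The lignin members called lower were 7 without mature root day 6 replicate 1, and the Casparian strip and suberin members 2 without mature root day 6 replicate 2.

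The mineral nutrient transporter list and the iron and metal list were lower in the tip as well. Mineral nutrient transporters had 8 of 44 members lower and 0 higher (13 and 0 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 7.38e-04, and adjusted p = 0.0375 with an estimated correlation). The sulfate transporter genes LOC_Os01g45830 and LOC_Os03g09980-ext had log2 fold changes of -4.53 (SE 0.62) and -2.9 (SE 0.52). Iron and metal homeostasis genes had 14 of 55 members lower and 2 higher (18 and 4 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 1.82e-04, and adjusted p = 0.0322 with an estimated correlation). The metallothionein LOC_Os01g74300, a small metal-binding protein, had 21.6 ± 24.7 CPM in the tip (SD, n = 6) and 725 ± 596 CPM in mature root (SD, n = 4), and the metallothionein LOC_Os12g38300-ext had 34.4 ± 26.4 and 473 ± 217 CPM. Metallothionein genes can share reads with close copies. The nutrient transporters called lower were 5 without mature root day 2 replicate 1 or either mature root day 6 replicate, and the iron and metal genes 9 without mature root day 6 replicate 2.

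Of the hormone lists, those of cytokinin, gibberellin and ethylene were lower in the tip, and those of auxin, jasmonate and abscisic acid did not pass camera but passed fry as lower (adjusted p = 0.0203, 0.0184 and 0.0462). Cytokinin genes had 11 of 33 members lower (12 adjusted over the list alone, with 1 higher), with a median of -0.97 (camera adjusted p = 1.85e-03, and adjusted p = 0.0384 with an estimated correlation). The members with the smallest p were described as cytokinin glucosyltransferases, a name given to many sugar transferases: LOC_Os02g51910 at log2 -4.01 (SE 0.52), and LOC_Os04g44250 with 2 counts in the tip and 77 in mature root, a ratio of 36 with a 95% counting interval from 9.63 to 302. The call of LOC_Os04g44250 was lost without mature root day 6 replicate 1 (adjusted p = 0.071) and with the replicate number as a block overall or within day. Gibberellin genes had 13 of 48 members lower and 2 higher (15 and 2 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.93e-04, and adjusted p = 0.0375 with an estimated correlation). Both leading members, LOC_Os11g13570 and LOC_Os07g44890, carry the description gibberellin receptor GID1L2, which belongs to a wide family of carboxylesterase-like proteins. They stood at 0.693 ± 0.812 and 0.325 ± 0.373 CPM in the tip (SD, n = 6) and at 30.4 ± 14.6 and 30.2 ± 37.6 CPM in mature root (SD, n = 4). LOC_Os07g44890 rested on 3 counts in the tip, a ratio of 87.6 with a 95% counting interval from 29.7 to 427. Ethylene genes had 8 of 26 members lower and 0 higher (the same counts adjusted over the list alone), with a median of -0.8 (camera adjusted p = 2.85e-04, and adjusted p = 0.0375 with an estimated correlation). The oxidases of the ethylene precursor LOC_Os02g53180-ext and LOC_Os05g05680 had log2 fold changes of -5.49 (SE 0.69) and -5.97 (SE 0.9). Without mature root day 2 replicates 1 and 2 and mature root day 6 replicates 1 and 2, in this order, 5, 3, 3 and 4 ethylene members and 5, 5, 2 and 5 cytokinin members were called lower. Cytokinin members were 6 without root tip day 2 replicate 2, and gibberellin members 7 without mature root day 6 replicate 1.

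WRKY transcription factors had 16 of 61 members lower and 0 higher (26 and 0 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 5.64e-06, and adjusted p = 0.0384 with an estimated correlation). The WRKY members called lower were 9 and 7 without mature root day 2 replicates 1 and 2, 4 without mature root day 6 replicate 1 and 10 without root tip day 6 replicate 2. OsWRKY9 (LOC_Os01g18584) had 0.402 ± 0.444 CPM in the tip (SD, n = 6) and 35.3 ± 19.1 CPM in mature root (SD, n = 4), and OsWRKY81 (LOC_Os11g45850) had 15.5 ± 6.99 and 76.3 ± 30.6 CPM. NAC transcription factors had 16 of 54 members lower and 0 higher (25 and 1 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 3.06e-06, and adjusted p = 0.0375 with an estimated correlation), led by LOC_Os03g21060-ext at log2 -4.66 (SE 0.62) and LOC_Os04g52810 at log2 -3.66 (SE 0.53). The NAC members called lower were 10 and 5 without mature root day 2 replicates 1 and 2, and 5 and 9 without mature root day 6 replicates 1 and 2. Pathogenesis-related genes had 21 of 68 members lower and 7 higher (22 and 9 adjusted over the list alone), with a median of -0.47, a camera adjusted p = 0.0205 and an adjusted p = 0.145 with an estimated correlation. That list lost its call without root tip day 2 replicate 2, at an adjusted p = 0.0531. The chitinases CHIT8 (LOC_Os06g51060) and CHIT14 (LOC_Os10g39680) had log2 fold changes of -5.65 (SE 0.59) and -5.12 (SE 0.64). The pathogenesis-related members called lower were 13 without mature root day 2 replicate 2, and 10 and 13 without mature root day 6 replicates 1 and 2.

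Photosynthesis genes as a list were far lower in the tips than in the mature root pools. Of 44 members tested, 36 were lower in the tip and 0 higher (37 and 1 adjusted over the list alone), and 6 had 0 counts in the 6 tip libraries together. The median log2 fold change was -6.62, or -6.19 with those 6 genes at the bound that 3 counts over the group allow (camera adjusted p = 3.54e-62, and adjusted p = 0.0121 with an estimated correlation). The summed level of the list was 5433 ± 2390 CPM in mature root (SD, n = 4), with libraries between 3337 and 8731 CPM, and 273.3 ± 129 CPM in the tip (SD, n = 6), with libraries between 151.6 and 495.7 CPM. This 19.9-fold difference had an exact two-sided permutation p = 4.76e-03 over 210 splits of the 10 libraries, the smallest p that 4 against 6 libraries allow. Among chlorophyll a-b binding proteins, which hold the pigments of the light-harvesting antenna, LOC_Os01g41710-ext had 1.21 ± 1.02 CPM in the tip and 633 ± 309 CPM in mature root, and LOC_Os04g38410 had 1.27 ± 1.2 and 382 ± 180 CPM. LOC_Os06g21590 had 1 count in the tip against 5291 in mature root, a ratio of 4950 with a 95% counting interval from 887 to 195000. LOC_Os02g10390, with 0 counts in the tip and 1209 in mature root, was at least 377-fold lower in the tip, and LOC_Os08g33820 had 2 counts against 1644. The small subunit of the carbon-fixing enzyme Rubisco, LOC_Os12g19381-ext, had 1 count against 1180, and the photosystem I subunit III gene LOC_Os03g56670-ext had 1 count against 1372. An iron-sulfur cluster binding protein gene outside the list, LOC_Os08g01380, had 0 counts against 943 and was at least 294-fold lower in the tip. Chlorophyll a-b binding and Rubisco small-subunit genes have close copies, so the values of single members are uncertain.

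**Figure D3:**
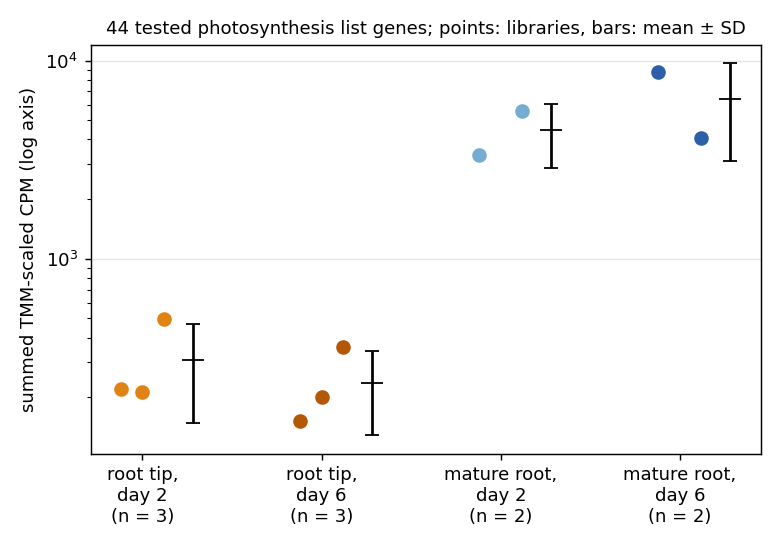
Summed TMM-scaled CPM of the 44 tested photosynthesis genes per library, on a log axis, by group. Points are libraries and bars the mean ± SD (n = 3 per root tip group, n = 2 per mature root group); the 4 mature root libraries lie between 3337 and 8731 CPM and the 6 tip libraries between 151.6 and 495.7 CPM.

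The other 13 tested lists did not pass camera between the tissues. Their medians were 0.44 for cyclins (adjusted p = 0.0607), 0.68 for xyloglucan enzymes (adjusted p = 0.149), -0.21 for cellulose synthases (adjusted p = 0.755), -0.08 for pectin enzymes (adjusted p = 0.283), -0.37 for class III peroxidases (adjusted p = 0.121) and 0.14 for aquaporins (adjusted p = 0.824). For jasmonate genes the median was -0.48 (adjusted p = 0.0607), for meristem regulators 0.37 (adjusted p = 0.0698) and for genes of fermentation and low oxygen -0.36 (adjusted p = 0.385). In 4 lists the median and the mean differed in sign: auxin genes (0.1 and -0.2, adjusted p = 0.829), abscisic acid and dehydration genes (0.28 and -0.33, adjusted p = 0.0853), heat shock proteins (0.02 and -0.19, adjusted p = 0.829) and secondary wall and xylem proteases (0.19 and -0.3, adjusted p = 0.728). Single members of such lists were called both ways, for example 6 of 92 peroxidases higher and 19 lower in the tip, and 3 of 99 auxin genes higher and 12 lower. By fry, 8 of the 13 lists passed: cyclins and meristem regulators as higher in the tip, and cellulose synthases, pectin enzymes, class III peroxidases, auxin, jasmonate and abscisic acid genes as lower. Fry makes no comparison with other genes, so these passes do not show that the lists differ from the rest. The circadian clock list had 1 member and was not tested.

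**Figure D4:**
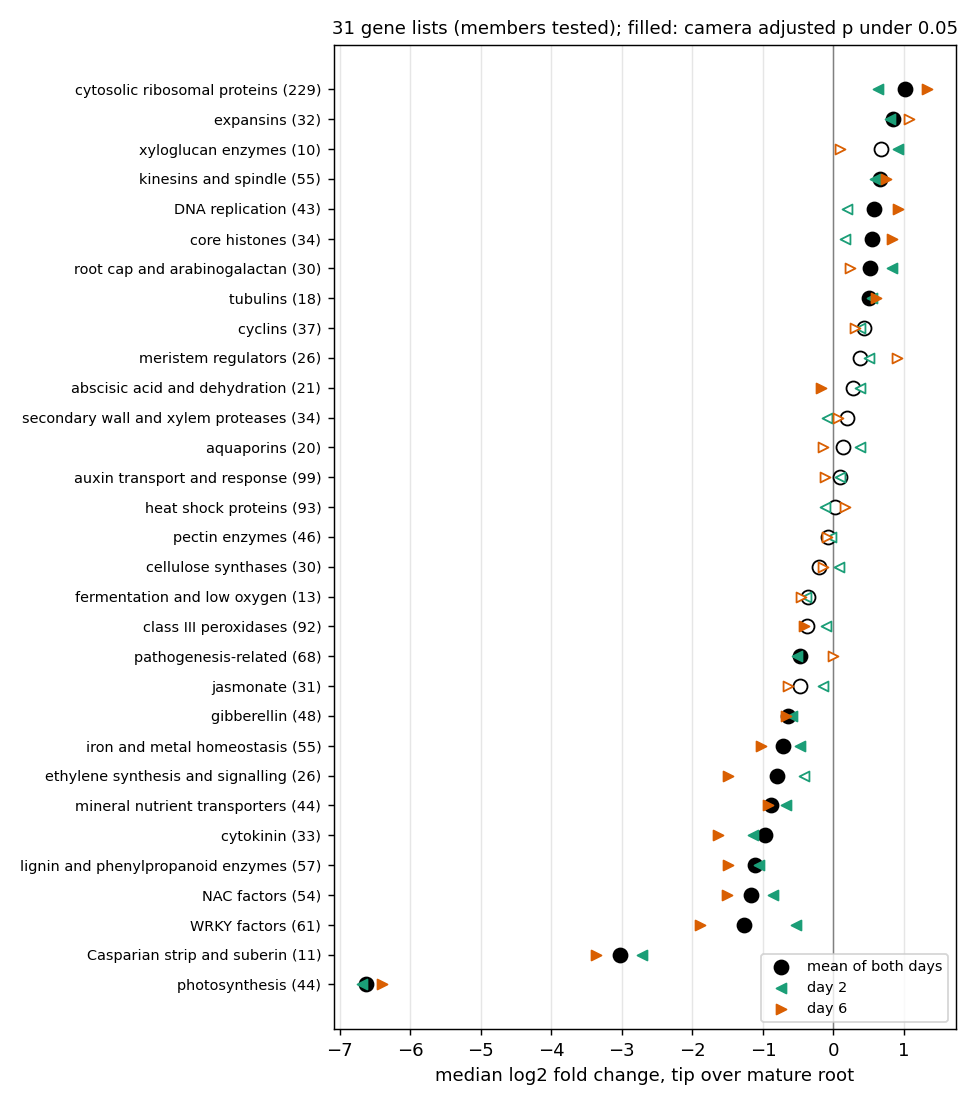
Median log2 fold change of tip over mature root for the 31 gene lists tested (members tested in parentheses), for the mean of both days (circles), day 2 (left triangles) and day 6 (right triangles). Filled symbols passed camera; photosynthesis lies at -6.62, -6.68 and -6.4, and cytosolic ribosomal proteins at 1.01, 0.63 and 1.33.

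On day 2 fewer genes were called between the tissues than over both days. Photosynthesis genes were lower in the tip in 26 of 44 members, with a median log2 fold change of -6.68 (36 adjusted over the list alone). LOC_Os08g44360, the fatty acyl reductase family gene, was at 2.15 ± 2.31 CPM in the tip (SD, n = 3) and 279 ± 120 CPM in mature root (SD, n = 2), and the metallothionein LOC_Os01g74300 at 4.07 ± 3.01 and 1180 ± 476 CPM. The tubulin LOC_Os02g07060-ext was among the genes higher in the tip, at 1500 ± 484 against 423 ± 22.9 CPM. In total 16 genes were higher and 205 lower in the tip by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all of them at least 2-fold, and 3212 had an unadjusted p under 0.05. By camera 6 lists were higher and 10 lower in the tip, and the photosynthesis list alone passed with an estimated correlation (adjusted p = 0.0111); the highest such p among the 16 was 0.335. Cytosolic ribosomal proteins had a median of 0.63 and 0 members called. Without root tip day 2 replicate 3, 10 lists passed. The count of genes fell to 54, 42 and 64 without root tip day 2 replicates 1, 2 and 3, to 47 without mature root day 2 replicate 2, and to 91 and 93 without mature root day 6 replicates 1 and 2. With only the day 2 libraries in the fit it was 4, all lower in the tip. DESeq2 called 237 higher and 797 lower, and edgeR without the filter on low counts 487 higher and 1247 lower, so the share of genes higher in the tip was 7.24%, 22.9% or 28.1% by the method.

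On day 6 there were 255 genes higher and 1106 lower in the tip, of which 1360 differed at least 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ribosomal protein genes now had 63 of 229 members higher and 2 lower (137 and 4 adjusted over the list alone), with a median of 1.33, among them LOC_Os08g13690-ext at 2130 ± 424 CPM in the tip (SD, n = 3) and 567 ± 92 CPM in mature root (SD, n = 2). The phenylalanine ammonia-lyase LOC_Os05g35290 had 23.1 ± 13.5 and 461 ± 201 CPM, OsWRKY9 (LOC_Os01g18584) 0.56 ± 0.488 and 50.7 ± 5.34 CPM, and the chitinase CHIT8 (LOC_Os06g51060) 1.57 ± 1.14 and 152 ± 78.2 CPM. Photosynthesis genes were lower in the tip in 31 of 44 members and WRKY factors in 11 of 61, with medians of -6.4 and -1.89. By camera 5 lists were higher and 12 lower, and 11 of the 17 passed with an estimated correlation; the highest such p among the 17 was 0.25. Without mature root day 6 replicate 1 there were 1 gene higher and 112 lower, and without replicate 2 there were 28 higher and 790 lower, so at most 1 or 28 of the 63 ribosomal protein genes could be among them. The count of genes fell to 379 and 748 without root tip day 6 replicates 2 and 3, and to 863 and 843 without mature root day 2 replicates 1 and 2. With only the day 6 libraries in the fit 30 genes were higher and 566 lower, that is 5.03% higher in the tip against 18.7% in the fit of all libraries. DESeq2 called 905 higher and 1836 lower.

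The calls of both days overlapped. They came from a fit that shared its estimate of spread over all 10 libraries, so the lists of calls were not independent. Fisher's exact test across genes, which treats them as independent, gave p = 2.77e-161 for genes lower and p = 6.85e-10 for genes higher in the tip and overstates the overlap. Of the 205 genes lower in the tip on day 2, 161 were also called lower on day 6, where lists drawn at random would share 11.8. Of the 16 higher in the tip on day 2, 7 were called higher on day 6, where lists drawn at random would share 0.212. The fold change had the same direction on day 6 for 202 of the 205 and 16 of the 16, and 0 genes were called in opposite directions.

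In the root tip, 0 genes differed between day 6 and day 2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in which the lowest adjusted p was 0.425. There were 2063 genes with an unadjusted p under 0.05, 10.7% of those tested, and DESeq2 called 130. As sets, core histones had a median log2 change of 0.38 and ribosomal proteins of 0.23, both with a camera adjusted p = 0.0321 and an adjusted p = 0.617 with an estimated correlation. Pathogenesis-related genes had a median of 0.36 (camera adjusted p = 0.0321, and adjusted p = 0.489 with an estimated correlation) and ethylene genes of -0.66 (camera adjusted p = 0.0344, and adjusted p = 0.489 with an estimated correlation). None of the 4 passed fry (adjusted p of 0.241 to 0.334). When libraries were scaled by their totals, all 4 lay just above the limit (camera adjusted p = 0.0501 each). The number of passing lists ranged from 0 without root tip day 6 replicate 3 to 7 without root tip day 2 replicate 1. The members with the smallest p did not pass on their own. The protease inhibitor gene LOC_Os01g04050 had 2.51 ± 1.54 CPM on day 2 and 28 ± 28.9 CPM on day 6 (SD, n = 3 each), with 61.1 CPM in root tip day 6 replicate 3. The endo-beta-glucanase gene LOC_Os07g35560-ext had 53.2 ± 14.6 and 236 ± 225 CPM, with 496 CPM in root tip day 6 replicate 1. The histone gene LOC_Os03g06670-ext had 62.3 ± 15.3 and 261 ± 232 CPM, with 524 CPM in root tip day 6 replicate 1, and the histone gene LOC_Os05g38740 had a log2 value of 0.93 (SE 0.36). The ribosomal protein genes LOC_Os01g54540-ext and LOC_Os11g05370 had log2 values of 2.64 (SE 0.73) and 1.36 (SE 0.4). Among ethylene genes, the oxidase homolog LOC_Os06g14400 had 14.7 ± 24.1 CPM on day 2 and 0.84 ± 0.733 CPM on day 6, and the signalling gene LOC_Os07g06300-ext, described as ethylene-insensitive protein 2, had 418 ± 345 and 147 ± 36.7 CPM. The higher values of both on day 2 rested on root tip day 2 replicate 2, at 42.5 and 816 CPM.

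In the mature root, 0 genes differed between the days in the same test, where the lowest adjusted p was 0.183, 2072 genes had an unadjusted p under 0.05 and DESeq2 called 375. Without mature root day 6 replicate 2 the count was 57, all higher on day 6, and without root tip day 6 replicate 1 it was 11. Gene lists moved nonetheless by camera: 12 were higher and 2 lower on day 6, with 0 of the 14 passing with an estimated correlation, where their lowest adjusted p was 0.0792 and their highest 0.237. Class III peroxidases, secreted enzymes of wall cross-linking, had a median log2 change of 1.12 (camera adjusted p = 2.56e-11, and adjusted p = 0.0792 with an estimated correlation), with 0 of 92 members called over all genes and 9 higher adjusted over the list alone. WRKY factors had a median of 0.83 (camera adjusted p = 6.57e-07) and lignin and phenylpropanoid enzymes of 0.86 (camera adjusted p = 5.29e-06). Cellulose synthases had a median of 0.71 (camera adjusted p = 0.0157), expansins of 0.54 (camera adjusted p = 6.54e-03) and the root cap and arabinogalactan list of 0.98 (camera adjusted p = 1.29e-03). With an estimated correlation these lists had an adjusted p of 0.0792, 0.105, 0.105, 0.181 and 0.237, in this order.

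Aquaporins, the water channels, had a median log2 change of 0.59 in the mature root from day 2 to day 6 (camera adjusted p = 7.8e-03, and adjusted p = 0.181 with an estimated correlation). Mineral nutrient transporters had a median of 0.38 (camera adjusted p = 5.15e-03, and adjusted p = 0.0792 with an estimated correlation), and iron and metal genes of 0.6 (camera adjusted p = 0.0104, and adjusted p = 0.105 with an estimated correlation). Cytokinin genes had a median of 0.61 (camera adjusted p = 6.97e-03, and adjusted p = 0.105 with an estimated correlation), ethylene genes of 0.61 (camera adjusted p = 0.0202, and adjusted p = 0.181 with an estimated correlation), and abscisic acid and dehydration genes of 1.45 (camera adjusted p = 0.0226, and adjusted p = 0.181 with an estimated correlation). The last list shares 7 genes with the root cap list. Cytosolic ribosomal proteins and DNA replication genes were lower on day 6, with medians of -0.45 (camera adjusted p = 5.29e-06) and -0.38 (camera adjusted p = 0.0269), and an adjusted p = 0.181 each with an estimated correlation. Scaling by library totals instead of TMM moved the median of all genes in this comparison to -0.11, and 15 lists passed under it. Leaving out mature root day 2 replicate 1 left 8 lists, and leaving out mature root day 6 replicate 2 left 6.

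No single gene of these lists passed the test between days in mature root. The peroxidase LOC_Os06g32990 had 0.643 ± 0.46 CPM on day 2 and 84.9 ± 15.1 CPM on day 6 (SD, n = 2 each), and the peroxidase LOC_Os05g04490 had 2.49 ± 1.27 and 68.3 ± 19.5 CPM. The phenylalanine ammonia-lyase LOC_Os05g35290 had 50.5 ± 21.5 and 461 ± 201 CPM, and the laccase LOC_Os12g15920 had 9.29 ± 1.92 and 102 ± 57.8 CPM. The sulfate transporter LOC_Os01g52130 had 0.318 ± 0.449 and 32.3 ± 5.55 CPM, and the nitrate transporter LOC_Os02g38230-ext had 7.52 ± 1.05 and 107 ± 79.1 CPM, with 163 CPM in mature root day 6 replicate 1 and 50.7 CPM in replicate 2. OsWRKY71 (LOC_Os02g08440-ext) had 57.7 ± 0.136 and 242 ± 26.6 CPM, and the cellulose synthases CESA9 (LOC_Os09g25490) and CESA8 (LOC_Os07g10770) had 48.3 ± 15.3 and 301 ± 214 CPM, and 104 ± 13.5 and 403 ± 332 CPM. Much of the rise of these cellulose synthases came from mature root day 6 replicate 1, at 452 and 638 CPM against 150 and 168 CPM in replicate 2. The aquaporins LOC_Os02g41860-ext and LOC_Os04g47220 had log2 values of 1.75 (SE 0.53) and 1.63 (SE 0.51). In the other direction, the ribosomal protein gene LOC_Os05g40820-ext had 408 ± 13.6 CPM on day 2 and 123 ± 30.1 CPM on day 6, and the DNA polymerase alpha gene LOC_Os01g64820 had 153 ± 192 and 4.58 ± 2.68 CPM, with 289 CPM in mature root day 2 replicate 2 and 17.1 CPM in replicate 1.

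The last comparison asked whether the difference between tip and mature root itself changed from day 2 to day 6. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes passed, the lowest adjusted p was 0.513, 1821 genes had an unadjusted p under 0.05, and DESeq2 called 94. Among described genes of at least 10 CPM, the smallest unadjusted p was that of the metallothionein LOC_Os01g74300, which was at 1180 ± 476 CPM in mature root on day 2 and 267 ± 32.6 CPM on day 6 (SD, n = 2 each), and at 4.07 ± 3.01 and 39.1 ± 24.3 CPM in the tip (SD, n = 3 each). The growth regulating factor gene LOC_Os02g53690 was at 117 ± 113 and 8.57 ± 3.91 CPM in mature root, with 197 CPM in mature root day 2 replicate 2 and 37.1 CPM in replicate 1, and at 14.7 ± 1.34 and 49.5 ± 16.3 CPM in the tip. The pfkB kinase gene LOC_Os03g06880 had a log2 difference of 5.81 (SE 1.07). The enoyl-CoA hydratase family gene LOC_Os02g43710-ext was at 9.63 ± 4.18 and 0.135 ± 0.191 CPM in mature root and at 6.63 ± 2.01 and 11.6 ± 3.2 CPM in the tip. The cytochrome P450 gene LOC_Os06g37300 was at 2.8 ± 0.534 and 104 ± 55.5 CPM in mature root, and at 2.03 ± 2.9 CPM in the tip on day 2 with 0 counts in the tip on day 6, so no fold is given. By camera 7 of the 31 lists differed between the days, 3 in favour of the tip on day 6 and 4 against, and 0 with an estimated correlation, where the lowest adjusted p was 0.246. Cytosolic ribosomal proteins had a median difference of 0.69 (camera adjusted p = 1.33e-07), and 0 of 229 members were called. Without mature root day 6 replicate 2, 4 lists passed.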

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

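The leave-one-library test of the ribosomal protein list and the gene-by-gene test of carried tip tissue were chosen only after the results were seen. For 7 gene lists camera with the preset correlation called a change of the contrast of tip with mature root between day 2 and day 6, but 0 of the 7 passed with an estimated correlation, where the adjusted p lay between 0.246 and 0.467, and 0 passed fry. The adjusted p from camera was 1.33e-07 for cytosolic ribosomal proteins, 2.98e-03 for core histones and 0.0127 for DNA replication, which moved towards the tip on day 6. It was 4.56e-04 for class III peroxidases, 6.59e-04 for ethylene synthesis and signalling, 9.4e-04 for WRKY factors and 0.0463 for abscisic acid and dehydration, which moved towards the mature root. The median differences were 0.69, 0.77 and 0.47 for the first 3 and -0.72, -1.44, -0.66 and -0.63 for the other 4.

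Cytosolic ribosomal protein genes differed more between the tissues on day 6 (median log2 1.33) than on day 2 (0.63) by camera, but the difference did not pass with an estimated correlation (adjusted p = 0.246) or by fry (adjusted p = 0.118), and 0 of 229 members were called. What follows applies to the pattern as camera called it. Short transcripts as the whole cause are argued against: the list's median difference of 0.69 lay above all of 10000 random lists matched on length and abundance (percentile 100). The highest of these reached 0.54. Their median was 0.22, against 0.084 for all genes, so matched genes shared part of the shift. Their members were drawn at random, so a list whose members vary together can lie outside them more easily. A single library is argued against as well, since without each of the 10 libraries in turn the camera adjusted p stayed at or below 2.37e-03, its value without mature root day 6 replicate 2. Tip tissue left in the mature root pools of day 2 is argued against as the whole cause, though by few genes. This holds only for carried tissue with the make-up of the whole tip sample, since the cap below assumes it. Such tissue would have to make up 41.5% of those pools (95% bootstrap interval 33.5 to 50.7). This caps the log2 difference of every gene on day 2 at 1.27, or at 1.58 for the lowest share of that interval. The interval resampled the genes of the list, which treats them as independent, and leaves out the spread between pools. A lower share, with a higher cap, is therefore not excluded. Of the 83 genes at least 8-fold higher in the tip on day 6, 7 had the lower 95% bound of their day 2 difference above 1.58. By chance 2.08 would be expected (exact one-sided binomial p = 4.84e-03, which treats genes as independent). On day 2, 36 of the 83 genes had at least 20 CPM in the tip, and so did 4 of the 7. Among these 4 the phytase gene LOC_Os04g24340-ext stood at 56.3 CPM in the tip and 1.85 CPM in mature root on day 2, and the armadillo repeat gene LOC_Os06g46995 at 93.1 and 2.8 CPM. The median of the 83 genes, 1.21 (95% bootstrap interval over genes 0.77 to 1.42, without the spread between pools), lay near the cap of the full share. As a set these genes, chosen by their day 6 values, therefore do not argue against carried tip tissue. On the first principal component the mature root libraries lay at 55.67 and 74.36 on day 2, nearer the tips than on day 6 (145.09 and 108.14). This does not tell carried tip tissue from a change of the mature root with days. A smaller share of tip tissue, or tissue from only a part of the tip, is not excluded. A change of the mature root between the days stays open and was not tested apart from carried tip tissue. Days in hydroponics and plant age cannot be told apart in such a change.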

How the results depend on the processing

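Thinned libraries and voom with sample weights were chosen after seeing the data. The counts of calls, in the order tissue over both days, tissue on day 2, tissue on day 6, time in tip, time in mature root and difference between days, were 2345, 221, 1361, 0, 0 and 0. With no filter on low counts they were 4063, 1734, 2981, 1002, 736 and 554. Of the 1002, 809 had been tested with the filter, and the other 9 splits of the 6 tip libraries into 3 and 3 gave 897 to 979 calls without the filter, so among the tip libraries such numbers arise without the filter in other splits too. The DESeq2 test gave 3569, 1034, 2741, 130, 375 and 94, and 52 to 116 in the other 9 splits of the tip libraries against the 130. Fits of only the compared groups gave 4 on day 2, 596 on day 6 and 3 for time in mature root, with fewer libraries for the estimate of spread, and voom gave 10 for time in mature root, where the cause was not tested. DESeq2 size factors, library totals, the 5 CPM filter, robust dispersion and thinning kept all 6 counts within 1.5 times.

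Leaving out 1 library at a time gave 845 to 2523 calls for tissue over both days, 42 to 312 on day 2, 113 to 1379 on day 6, 0 for time in tip in every case, 0 to 57 for time in mature root and 0 to 2 for the difference between days, the 2 without mature root day 6 replicate 2. Passing lists ranged from 17 to 22, 10 to 16, 16 to 18, 0 to 7, 6 to 16 and 4 to 9 in the same order, from 18, 16, 17, 4, 14 and 7. With an estimated correlation 10, 1, 11, 0, 0 and 0 lists passed, and fry passed 24, 15, 24, 0, 10 and 0. Scaling by totals passed 0 for time in tip, where the 4 lists lay just above the limit (camera adjusted p = 0.0501 each). Scaling by totals moved the median of all genes to -0.11 for time in mature root and to 0.103 for the difference between days. Of the 45 genes named as called between tissues, 34 kept their call under all settings in which they were tested. The other 11 lost it under at least 1, 10 of them higher in the tip. Of 360 counts of called list members under alternatives, 250 stayed within 1.5 times and 110 moved further. The ethylene-list gene LOC_Os08g30150-ext had a log2 change of 2.45 between days in mature root, which did not pass, and ranged from -0.49 without mature root day 6 replicate 1 to 3.36 without replicate 2 of that group.

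No pairing by replicate number was detected: deviations from the group means correlated at -0.045 to 0.023 for libraries of the same number and at -0.042 to 0.046 for other numbers. Each mature root group has 2 libraries, whose deviations mirror each other. The 2 ranges therefore hold in part the same values with the sign reversed, and the check has little power to show pairing. With the replicate number as a block the tissue counts were 1266, 135 and 579, with a block within day 1358, 86 and 598, and the 3 counts of the other contrasts stayed at 0 with the block. Replicate number 3 exists only in the tip, so with a block those libraries say little on the tissue contrast. The block also takes up residual degrees of freedom. How much this lowered the counts was not tested. Alternatives foreseen for normalized values were not run, since the table holds counts. Depth limits genes near 1 to 3 CPM, where 3 counts per library are reached.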

Other observations

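The test of rising light exposure, the families of shared description and, for genes far above the rest of their group, the tests of counting noise, of shared plants and of shared descriptions in their final form were chosen only after the results were seen. Among 195 families of at least 10 tested genes with the same description, mostly outside the lists above, 4 were higher and 13 lower in the tip by camera. Cytochrome P450 genes, a large class of oxidases, had 43 of 90 members lower in the tip and 0 higher, with a median log2 fold change of -1.7 (adjusted p = 3.87e-12, and adjusted p = 0.116 with an estimated correlation). Genes described as SCP-like extracellular proteins had 16 of 22 lower and 1 higher (median -4.02, adjusted p = 1.49e-10, and adjusted p = 0.296 with an estimated correlation). The 3-ketoacyl-CoA synthases, which lengthen fatty acids for wax and suberin, had 6 of 10 lower and 0 higher (median -3.05, adjusted p = 4.51e-04, and adjusted p = 0.283 with an estimated correlation). Peptide transporters of the PTR2 description had 10 of 34 lower and 0 higher (median -1.27, adjusted p = 7.01e-05, and adjusted p = 0.296 with an estimated correlation). In favour of the tip, LSM domain proteins, which act in RNA processing, had 4 of 22 members higher (median 0.96, adjusted p = 3.4e-04, and adjusted p = 0.283 with an estimated correlation). The T1 family peptidases, subunits of the proteasome core, had a median of 0.71 with 0 of 21 called (adjusted p = 5.8e-03, and adjusted p = 0.296 with an estimated correlation).

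Between days in mature root, 9 families were higher and 1 lower on day 6, again with 0 single genes called. The SCP-like proteins had a median log2 change of 2.7 (adjusted p = 2.13e-15, and adjusted p = 0.561 with an estimated correlation), glycosyl hydrolases of family 17 of 1.48 (adjusted p = 7.98e-08, and adjusted p = 0.108 with an estimated correlation) and cytochrome P450 genes of 1 (adjusted p = 7.12e-09, and adjusted p = 0.108 with an estimated correlation). In the tip the family 17 hydrolases passed alone, with a median of 1.24 (adjusted p = 4.41e-04, and adjusted p = 0.76 with an estimated correlation). Of the 637 transcribed regions without a description that were tested, 19 were higher and 24 lower in the tip, 6.75% against 12.4% of the gene models; their median length was 634 bases against 2385.

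The tissue calls were set against other splits of the libraries within days. Of 100 splits that put 2 libraries per day in the mature root group, only the real split gave as many as 2345 calls (1 of 100). The highest count among the others was 0. A share of 1 of 100 is the smallest that these splits allow. Every other split mixes tip and mature root libraries in at least 1 group, which widens the spread. Splits that exchanged 1 library also gave 0 calls. The 0 counts therefore do not show what chance alone would give, and chance is not excluded by them. For the passing lists the real split was also the only one with 18 (1 of 100), but others gave up to 17. The 17 were reached with 1 library exchanged and with 4, where a difference of tissue remains between the groups. Splits with 1 tip and 1 mature root library per day in the mature root group gave 0 to 9 lists. For the days in root tip there are 10 splits of 3 against 3, too few for a share under 0.05: the real count of calls was 0 and the highest other 0, reached in 10 of 10, and the real count of lists was 4 and the highest other 8, with 3 of 10 splits giving as many as the real one.

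Photosynthesis genes were 19.9-fold higher in summed CPM in mature root. Depth is argued against as the cause, since 33 members were called lower in the tip with all libraries thinned to the lowest total, against 36 at full depth. Pieces of shoot in the mature root pools are a possible source and cannot be told apart from expression in roots: the 36 members kept their ratios over the 4 mature root libraries about as well as random gene sets of like abundance (residual SD at percentile 32.6), and YABBY genes, fixed as leaf markers, were too rare to decide, with 1 of 7 tested, 0 called, and summed levels of 12.4 CPM in tip and 9.12 CPM in mature root. Light exposure that builds up with days in hydroponics also stays open, as the list did not pass between the days in mature root (median log2 0.24, camera adjusted p = 0.305). Such exposure was also not separable from plant age, which rose with the days. A difference between the tissues themselves was not tested.

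In every library some genes stood far above the other libraries of their group, at 20 CPM or more and at least 10 times each of the others. There were 1703 such pairs of gene and library, over 1653 genes, with 57 to 239 per library. Mature root groups hold fewer libraries (n = 2) than tip groups (n = 3), so the rule is looser there. Counts per library are therefore not comparable between the tissues. The highest of 20 Poisson draws around the group means gave 0 such pairs, but separate pools differ by more than the counting of reads, so this does not decide on noise from sampling molecules before amplification. Genes of the same description rising together in a pool stay open as well: pairs of the same description exceeded the median of random sets of like size and abundance in 6 of 10 libraries and their upper limit in 0 of 10. Plants shared by tip and mature root libraries of the same number and day stay open. Such libraries shared on average 1 of these genes and libraries of other numbers 1.5, at most 5 (exact one-sided permutation p = 0.833). The deviations of the 4 pairs of tip and mature root libraries of the same number and day from their group means correlated at -0.021 to 0.023. The 8 such pairs of the same day and other numbers gave -0.042 to 0.042. These are in part the same values with the sign reversed, since each mature root group has 2 libraries. They did not detect shared plants and do not exclude them. Uneven amplification over the 18 PCR cycles was not tested, and no biological explanation was tested.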
